A study of Rattus norvegicus with 9 samples.

How the data were processed

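Gene expression was profiled in 9 libraries of rat S31 vascular smooth muscle cells, 3 each for the control columns (LH-NS), the IGF-NS columns and the PDGF-NS columns. Per the labels' protocols, cells were starved of serum for 48 h, growth factors were given at 25 ng/ml, total RNA was taken with Trizol, and libraries were made with the Lexogen SENSE mRNA kit v2. Per the submitters' processing notes GSNAP and Cufflinks were used. Their versions and settings, the genome build and the annotation release are not given in the sources used here. The values the authors deposited are FPKM per gene and library, that is fragments per kilobase of transcript and unit of library size. They are not counts, so no count model was fitted, and the number of reads behind a value is unknown. Genes were used with the Ensembl identifiers and symbols that the table pairs with each other, and coordinates were not used here. Reads shared between near-identical genes could have been split in Cufflinks, which was not examined.

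Libraries were assigned to samples by the column name that each sample record gives. The records titled PDGF-BB name the IGF-NS columns and the records titled IGF-1 name the PDGF-NS columns, so both names are printed and the sets are called by their columns. By record the harvest was at 48 h for the IGF-NS columns and at 24 h for the PDGF-NS and control columns.

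The table held 26407 rows, of which 5795 had no symbol. The value 999999999 stood in 10 cells of 4 genes (Dync1h1, Dst, Dmpk and Plec). It was read as a failed estimate, and these genes were left out. Of duplicated identifiers, 2 all-zero rows were removed. A total of 10199 genes were listed at 0 in every library. In 31 genes with a median over 5 FPKM at least 1 library was listed at 0, so a listed 0 can be a failed estimate and not an absence. Transcripts of the mitochondrial genome did not pass the filter, and 0 were tested. Acta2 was not analysed here.

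Differential expression was tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with moderated variances that follow the mean (limma-trend), for genes with a mean of at least 1 FPKM over the 9 libraries. This left 11376 genes, 768 of them without a symbol. All 9 libraries entered one fit with the group as its only term, and 3 two-sided contrasts were taken. P-values were adjusted by the Benjamini-Hochberg method within a contrast, and genes with an adjusted p under 0.05 were called. Fold changes on this scale understate the change of low genes. Before the data were examined, 32 lists with 580 genes were fixed, covering smooth muscle, cell cycle, metabolic, matrix, signalling and stress genes and markers of other cell types. The 28 lists with at least 3 tested genes were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a contrast. Camera was repeated with the correlation estimated from the data, and fry was run as an alternative. With an estimated correlation, the calls that held were those of the contractile and the synthetic list in IGF-NS against control (11 calls with the preset, 2 with the estimate). In PDGF-NS against control 15 lists were called with the preset and 0 with the estimate, and between the treated sets 16 and 0. Fry, which asks only whether a list moved on balance one way, called 12, 18 and 15 lists.

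Genes were named by a rule fixed before the data were examined. For each contrast these were the 8 called genes with the largest rise and the 8 with the largest fall among genes with at least 5 FPKM in the higher group and no overlap between libraries, up to 4 called members of each list with the largest change, a fixed set of smooth muscle and receptor genes, and the 8 genes with the largest difference between the treated sets among those that moved in opposite directions. A gene outside this rule is said to have been chosen after its values were seen. The rule gave 223 genes. The text prints part of them, mainly those whose calls did not depend on the scaling or on a single library, and the others are not reported here.

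The procedure was tested on simulated data in which 200 of 11376 genes were changed, all of them with a mean log2(FPKM + 1) over 2. The simulated spread was the one limma had fitted. Recovery among lower genes was not measured. In IGF-NS against control it recovered 7.4% of the genes changed by 0.5 on the log2 scale, 89.4% of those changed by 1 and 98.5% of those changed by 2. In PDGF-NS against control it recovered 10.3%, 78.8% and 98.5%, and between the treated sets 7.4%, 71.2% and 97.0%. Of the unchanged genes 12, 6 and 3 were called in these comparisons. Far more genes were called in the real data, which makes the cutoff on the unadjusted p less strict there, so these shares do not give the recovery of small changes in the real comparisons. To see how far shared controls alone correlate the fold changes, 9 unchanged libraries were simulated 100 times and fitted in the same way.

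The alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a mean of at least 5 FPKM, quantile normalization, rescaling of every library to one common sum (TPM), median ratio scaling, limma without the variance trend or with robust moderation, the replicate number as a block, weights per library, a fit of the compared groups alone, a log2 fold change of at least 1, and leaving out each library. An alternative without genes listed at 0 in part of a group was added after seeing the data.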

Results

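Gene expression was measured by RNA sequencing in 9 libraries of S31 cells, primary vascular smooth muscle cells taken from small vessels of the heart of male Wistar Kyoto rats. The cells were starved of serum for 48 h and then received fresh serum-free medium alone (control) or medium with 25 ng/ml of either recombinant rat PDGF-BB or recombinant human IGF-1. PDGF-BB is a mitogen for smooth muscle and the classical repressor of its contractile genes, and IGF-1 acts through a receptor tyrosine kinase that signals mainly by way of PI3K and AKT. By the series' title, the question was whether microvascular smooth muscle cells change phenotype in different ways under these growth factors. Each of the 3 groups held 3 libraries, and the sources used here do not say whether these came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

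The sources disagree on which treated set is which. The sample records that name PDGF-BB, harvested at 48 h, point to the data columns called IGF-NS, and the records that name IGF-1, harvested at 24 h, point to the columns called PDGF-NS. Nothing in the expression values was used to settle this. The sets are therefore named by their columns throughout: the IGF-NS libraries are PDGF-BB at 48 h by record, and the PDGF-NS libraries are IGF-1 at 24 h by record. The controls, columns LH-NS, were harvested at 24 h, and a control at 48 h was not used here, so growth factor and time cannot be separated in the set that was harvested later.

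The authors' FPKM values summed to between 616899 and 748191 per library, and between 11049 and 11351 genes reached 1 FPKM. Read depth is not known, because the table holds FPKM and not counts. The steps between low values put the relative depth at 1.0 (set), 0.66 and 0.78 in control, 1.09, 0.72 and 1.16 in IGF-NS, and 0.95, 1.34 and 1.26 in PDGF-NS. Control libraries 2 and 3 and IGF-NS library 2 were thus the shallowest. The controls also had the fewest genes at 1 FPKM, 11049 to 11141, against 11213 to 11307 in IGF-NS and 11269 to 11351 in PDGF-NS. Whether depth bears on rises from low values was not tested. Across genes, libraries of a set correlated with Pearson r of 0.959 to 0.983 and libraries of different sets with 0.901 to 0.947. Below, levels are mean FPKM ± SD of 3 libraries, fold changes are on the log2(FPKM + 1) scale ± SE from limma, and adjusted p-values are from limma with Benjamini-Hochberg adjustment over 11376 genes. This scale understates the change of genes with low FPKM. Changes written with the ending -fold are ratios of mean FPKM instead.

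**Figure D1:**
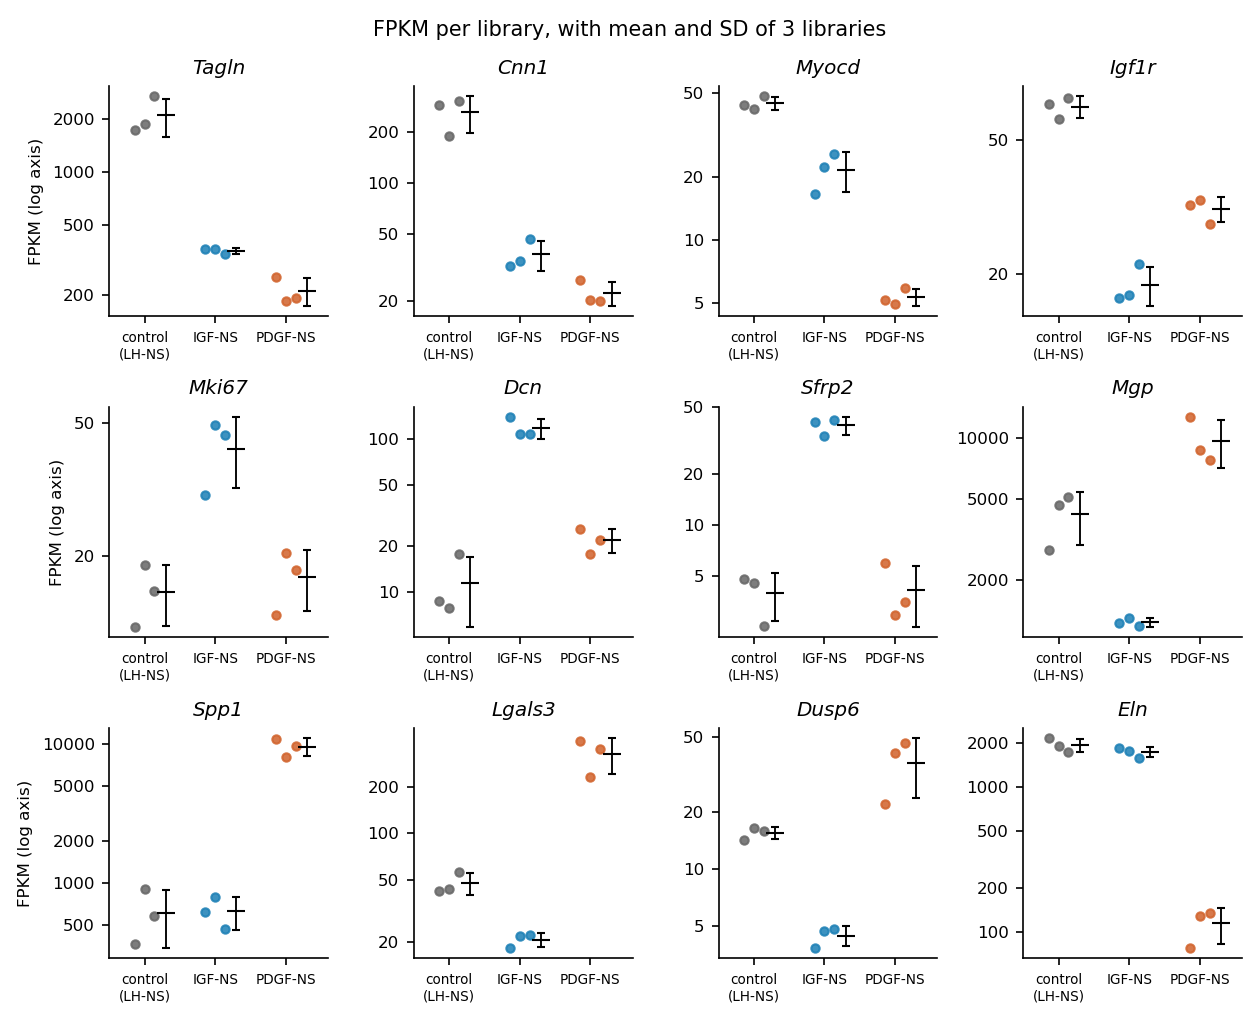
FPKM of 12 genes in each of the 9 libraries on a log axis, with the mean and SD of each set of 3 beside the points. Tagln, Cnn1 and Myocd lay below control in both treated sets, Mki67 lay above control in the IGF-NS libraries (PDGF-BB by record), and Spp1 and Lgals3 lay above control in the PDGF-NS libraries (IGF-1 by record).

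The first comparison set the IGF-NS libraries (PDGF-BB, 48 h, by record) against control. Of 24 contractile genes 17 fell (adjusted p = 0.039 with an estimated correlation), and of 26 genes of the G2 and M phases 21 rose (adjusted p = 0.4 with an estimated correlation). Tagln, which encodes the actin-binding protein SM22 alpha (ENSRNOG00000017628), went from 2110 ± 518 to 358 ± 13.6 FPKM (SD, n = 3), a log2 fold change of −2.53 ± 0.18 with adjusted p = 3.3e-05. The largest rise among the genes named by rule was that of Lrrc17, a secreted leucine-rich repeat protein (ENSRNOG00000012817), from 1.69 ± 0.516 to 143 ± 40 FPKM (5.72 ± 0.21, adjusted p = 9.1e-07).

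Of 24 contractile and cytoskeletal differentiation genes tested, 0 rose, 17 fell and 7 did not pass, against 1 higher and 20 lower adjusted over the list alone. Their median log2 fold change was −1.30 (camera adjusted p = 4.6e-20, and adjusted p = 0.039 with an estimated correlation). Cnn1, the smooth muscle calponin, was 6.88-fold lower than in control, falling from 262 to 38 FPKM (log2 −2.74). Csrp1, a LIM-domain partner of the actin cytoskeleton, fell by 2.68 on the log2 scale, and Itga8, the integrin alpha 8 chain, fell by 2.52. Myocd, the coactivator of serum response factor that drives contractile genes, fell from 44.7 ± 3.16 to 21.5 ± 4.6 FPKM, a log2 fold change of −1.04. Smtn, which encodes smoothelin, did not pass (−0.60, adjusted p = 0.054). Myh11, the smooth muscle myosin heavy chain, had means of 1.77 FPKM in control, 0.405 in the IGF-NS and 0.654 in the PDGF-NS libraries, which is under the filter, and Acta2 was not analysed here.

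Genes of TGF-beta, BMP and endothelin signalling fell more often than they rose. Of 24 tested, 2 rose, 11 fell and 11 did not pass, with 2 higher and 15 lower adjusted over the list alone and a median of −0.81 (camera adjusted p = 6.1e-09, and adjusted p = 0.052 with an estimated correlation). The matricellular genes Ctgf (−3.87) and Cyr61 (−3.63) fell, as did Edn1, the precursor of the vasoconstrictor endothelin-1 (−2.67, 15.5 to 1.65 FPKM). ERK-induced and immediate-early genes lay below control too: of 22, 0 rose, 15 fell and 7 did not pass (0 higher and 16 lower adjusted over the list alone). Their median was −1.14 (camera adjusted p = 5.6e-12, and adjusted p = 0.1 with an estimated correlation). Dusp1 and Dusp6, phosphatases that inactivate MAP kinases, fell by 3.35 and 1.60 on the log2 scale, and Fosl1, the AP-1 subunit Fra-1, fell by 1.83. Heat shock and early stress genes, which handling also induces, fell in 2 of 11 and rose in 1 (1 higher and 3 lower adjusted over the list alone), with a median of −0.41 (camera adjusted p = 0.016, and adjusted p = 0.36 with an estimated correlation). That call ended with a mean of at least 5 FPKM (0.15) and without control library 3 (0.05), and 6 members fell under median ratio scaling and 4 under quantile normalization.

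The list of genes reported for the dedifferentiated, or synthetic, smooth muscle state fell as well. Of its 17 tested members 0 rose, 11 fell and 6 did not pass (0 higher and 11 lower adjusted over the list alone), with a median of −1.01 (camera adjusted p = 2.6e-09, and adjusted p = 0.039 with an estimated correlation). The members that fell included Mgp, matrix Gla protein, an inhibitor of calcification (4190 to 1230 FPKM, log2 −1.72), Thbs1, thrombospondin 1 (−2.29), and Tnfrsf11b, the decoy receptor osteoprotegerin (−2.11). Spp1, osteopontin, a common marker of that state, had a log2 fold change of 0.10 with adjusted p = 0.85, and the transcription factor Klf4 one of 0.28 with adjusted p = 0.34. Bone and cartilage genes were not called as a list: of 7, 1 rose, 3 fell and 3 did not pass (2 higher and 3 lower adjusted over the list alone). Their median was −0.03 (camera adjusted p = 0.15), and it turned to 0.01 after rescaling to one common sum. With no filter on low values the list was called lower (0.024). Acan, the cartilage proteoglycan aggrecan, fell by 2.16 and Sox9, a transcription factor of cartilage, by 1.18 on the log2 scale.

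Genes of the G2 and M phases rose together. All but 5 of 26 passed, with 26 higher and 0 lower adjusted over the list alone: 21 rose and 0 fell. The median was 0.98, or 0.86 after median ratio scaling (camera adjusted p = 4.3e-08, and adjusted p = 0.4 with an estimated correlation). Mki67, the Ki-67 proliferation antigen, rose from 15.6 ± 3.22 to 41.8 ± 9.97 FPKM (1.36 ± 0.22, adjusted p = 0.0024), and Cenpf, a kinetochore protein, Nusap1, a spindle protein, and Kif20a, a kinesin of cytokinesis, rose by 1.30, 1.28 and 1.26. The G1/S and DNA replication list did not pass as a list: of 28 genes, 3 rose, 4 fell and 21 did not pass (3 higher and 4 lower adjusted over the list alone), with a median of −0.14 and camera adjusted p = 0.12. Rescaling every library to one common sum gave that list a lower call, adjusted p = 0.049, and so did using no filter on low values (0.035) and leaving out control library 3 (0.033) or IGF-NS library 3 (0.042).

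Among interstitial matrix genes, 8 of 24 rose, 1 fell and 15 did not pass (9 higher and 1 lower adjusted over the list alone). The median was 0.27 and the list was not called (camera adjusted p = 0.12), although quantile normalization (0.0063), no filter on low values (0.024) and leaving out control library 1 (0.049) called it higher. Dcn, the collagen-binding proteoglycan decorin, rose 10.3-fold, from 11.4 ± 5.51 to 117 ± 17.7 FPKM (3.33 ± 0.27). Its relative Lum, lumican, rose by 2.41, Tgfbi, a matrix protein named for its induction by TGF-beta, by 2.32, and Col3a1, a chain of fibrillar collagen, by 1.32. Dcn and Lum also stand in the list of fibroblast markers, of which 4 of 9 rose, 1 fell and 4 did not pass (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.12); another member, Pdgfra, a PDGF receptor, rose by 0.85. Of 11 basement membrane genes, 0 rose, 4 fell and 7 did not pass (0 higher and 4 lower adjusted over the list alone), with a median of −0.36 (camera adjusted p = 0.0032, and adjusted p = 0.4 with an estimated correlation). The laminin chains Lama5 (−1.04) and Lamb2 (−0.96) were among those that fell.

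Other groups moved in part. Of 16 genes of proteolysis and migration, 5 rose, 6 fell and 5 did not pass (5 higher and 7 lower adjusted over the list alone), with 3 rising under median ratio scaling and under quantile normalization. Mmp2, a gelatinase, rose by 2.17, and Plaur, the urokinase receptor, fell by 1.31. The lower call of that list (camera adjusted p = 0.041, and adjusted p = 0.36 with an estimated correlation) ended under quantile normalization (0.11), under median ratio scaling (0.13), with a mean of at least 5 FPKM (0.054), and without control library 1 (0.092), IGF-NS library 2 (0.053) or IGF-NS library 3 (0.062). Among 15 chemokine, cytokine and NF-kB genes, 3 rose, 3 fell and 9 did not pass (3 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.43). Vcam1 rose by 2.46 while Icam1 fell by 1.62, both of them adhesion molecules for leukocytes. For fatty acid synthesis and desaturation, 6 rose, 0 fell and 5 did not pass of 11 (7 higher and 0 lower adjusted over the list alone), with a median of 0.50, or 0.36 after median ratio scaling (camera adjusted p = 0.0042, and adjusted p = 0.4 with an estimated correlation). Under median ratio scaling and under quantile normalization 3 rose. The desaturases Fads1 and Scd rose by 1.56 and 1.58. Of 23 cholesterol genes 1 passed, and 0 did adjusted over the list alone (camera adjusted p = 0.43), though without control library 2 the list was called higher (0.0048). For glycolysis, 1 rose, 2 fell and 13 did not pass of 16 (1 higher and 2 lower adjusted over the list alone), and the median of 0.10 turned to −0.04 under median ratio scaling (camera adjusted p = 0.47). The 1 that rose was Bnip3 (1.01), a member of that list that encodes no glycolytic enzyme. Interferon-stimulated genes rose in 8 of 16 and fell in 0 (9 higher and 0 lower adjusted over the list alone), with a median of 0.50, or 0.35 after median ratio scaling (camera adjusted p = 0.01, and adjusted p = 0.36 with an estimated correlation). IFI44, an interferon-induced protein, rose by 2.08.

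Components of the growth factor pathways changed as well. Igf1r, the IGF-1 receptor, fell from 62.6 ± 4.59 to 18.6 ± 2.45 FPKM (−1.70 ± 0.13, adjusted p = 4e-05), and Irs2, an adaptor of that receptor, fell by 2.38 on the log2 scale. Irs1 had a log2 fold change of −0.43 (adjusted p = 0.23) and Pdgfrb one of 0.10 (adjusted p = 0.74). The binding proteins Igfbp5 and Igfbp4 rose by 3.52 and 2.37, and Stc1, stanniocalcin 1, by 2.46. As lists, neither the 16 genes of the IGF axis (5 rose, 3 fell and 8 did not pass; 5 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.78) nor the 7 genes of the PDGF axis (1 rose, 1 fell and 5 did not pass; 2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.78) were called, and the PDGF axis median of 0.10 turned to −0.06 under median ratio scaling.

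Further genes were named for the size of their change alone. Pi15, a peptidase inhibitor, rose by 4.03, Adh1, an alcohol dehydrogenase, by 3.76, Dlg2, a membrane scaffold, by 3.66, and G0s2, an inhibitor of triglyceride lipase, by 3.65. Sfrp2, a secreted modulator of Wnt signalling, rose from 3.94 to 38.9 FPKM (3.04). Acta1, skeletal alpha-actin, fell by 4.16, Lmcd1, a LIM-domain cofactor, by 4.49, Nkd2, a Wnt antagonist, by 4.04, and St8sia2, a polysialyltransferase, by 3.42. Pln, phospholamban, which restrains the calcium pump of the sarcoplasmic reticulum, fell by 3.59. It stands on the cardiomyocyte marker list, and of the 2 members tested there 0 rose, 1 fell and 1 did not pass.

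In all, 1976 genes lay higher and 851 lower than control, a total of 2827. The log2 fold change was at least 1 in size in 435 higher and 353 lower genes. The median of all genes was 0.15, and median ratio scaling removed this shift and gave 1143 higher and 1222 lower, or 48.3% higher in place of 69.9%. Quantile normalization gave 1214 and 1171, whereas rescaling to one common sum left the median at 0.15 and gave 1909 and 893, or 68.1% higher. Median ratio scaling and quantile normalization take out such a shift by design, whatever its cause. Of the genes lower as deposited 850 of 851 stayed lower under median ratio scaling, and of the higher ones 1143 of 1976 stayed higher. That scaling shifts the fold changes downward here, so lower calls could hardly be lost and their number adds no support. The log2 values given above include the 0.15 shift.

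The second comparison set the PDGF-NS libraries (IGF-1, 24 h, by record) against control. Elastin fell and osteopontin and galectin-3 rose. Of 24 contractile genes 20 fell and 2 rose (adjusted p = 0.11 with an estimated correlation), and 5 of 7 bone and cartilage genes rose (adjusted p = 0.11 with an estimated correlation). Spp1, osteopontin (ENSRNOG00000043451), went from 618 ± 272 to 9480 ± 1390 FPKM (SD, n = 3), 15.3-fold, with a log2 fold change of 4.02 ± 0.31 and adjusted p = 1.5e-05. Eln, elastin (ENSRNOG00000001469), went from 1950 ± 207 to 115 ± 32.1 FPKM (−4.11 ± 0.20, adjusted p = 1.9e-06). The largest rises were those of Igfbp5 (0.743 to 90.4 FPKM, 5.56) and of Hsd11b1, the enzyme that regenerates active glucocorticoid (18 to 852 FPKM, 5.50).

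Of the 24 contractile genes, 2 rose, 20 fell and 2 did not pass (2 higher and 21 lower adjusted over the list alone), with a median of −1.57 (camera adjusted p = 2.5e-16, and adjusted p = 0.11 with an estimated correlation). Tagln fell to 211 ± 37.5 FPKM (−3.30 ± 0.18) and Cnn1 to 22.5 ± 3.69 FPKM (−3.47 ± 0.21). Myocd fell 8.38-fold, to 5.34 ± 0.497 FPKM (log2 −2.85 ± 0.16, adjusted p = 3.6e-06). Actg2, the smooth muscle gamma-actin, fell by 2.68 and Smtn by 1.06 on the log2 scale. The members that rose were Des, the intermediate filament protein desmin (1.30), and Hspb6, a small heat shock protein of muscle (0.65, chosen after its values were seen). Cardiomyocyte markers also fell, 2 of 2: Pln (−3.38) and Tnnt2, cardiac troponin T (−2.15).

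TGF-beta, BMP and endothelin genes fell in 13 of 24 cases, rose in 3 and did not pass in 8 (3 higher and 15 lower adjusted over the list alone). Their median was −0.89 (camera adjusted p = 2.2e-06, and adjusted p = 0.11 with an estimated correlation). Tgfb3, a TGF-beta ligand, fell by 2.73 and Ctgf by 3.21, whereas Ednra, an endothelin receptor, rose from 6.66 ± 0.363 to 68.1 ± 6.58 FPKM (3.17). The ERK-induced list split: of 22, 8 rose, 4 fell and 10 did not pass (11 higher and 4 lower adjusted over the list alone), and it was not called (camera adjusted p = 0.68). Dusp5, a nuclear ERK phosphatase, rose by 3.22 and Fosl1 by 1.97, and Dusp1 fell by 2.55 and the transcription factor Myc by 2.08.

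Synthetic-state genes also went both ways. Of 17, 6 rose, 8 fell and 3 did not pass (7 higher and 9 lower adjusted over the list alone; camera adjusted p = 0.19). Lgals3, the lectin galectin-3, rose from 47.4 ± 7.66 to 325 ± 83.7 FPKM (2.73 ± 0.20), next to Spp1, while Eln and Thbs1 (−1.62) fell. Mgp, which fell in the IGF-NS libraries, rose here to 9680 ± 2570 FPKM (1.22). Bone and cartilage genes rose in 5 of 7 cases and fell in 0 (6 higher and 0 lower adjusted over the list alone), with a median of 1.03, or 0.89 after median ratio scaling (camera adjusted p = 0.0021, and adjusted p = 0.11 with an estimated correlation). Apart from Spp1 they included Sox9 (1.51), the osteoblast transcription factor Runx2 (1.33) and the pyrophosphate-forming enzyme Enpp1 (1.03). With no filter on low values, which adds members with a mean under 1 FPKM, the median was 0.17 and that list was not called (0.42).

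Matrix genes fell on balance. Of 24 interstitial matrix genes, 5 rose, 9 fell and 10 did not pass (7 higher and 9 lower adjusted over the list alone), with a median of −0.24 (camera adjusted p = 0.018, and adjusted p = 0.48 with an estimated correlation). The call ended under quantile normalization (0.08). Lox, the lysyl oxidase that crosslinks elastin and collagen, fell from 490 ± 44.1 to 111 ± 15.4 FPKM (−2.14), but Tgfbi rose by 4.72 and Col6a3, a collagen VI chain, by 2.57. Basement membrane genes fell in 5 of 11 and rose in 0 (0 higher and 5 lower adjusted over the list alone). Their median was −0.41 (camera adjusted p = 0.0012, and adjusted p = 0.48 with an estimated correlation), with Nid1, nidogen 1, at −1.34 and Col4a1, a collagen IV chain, at −1.19. Fibroblast markers rose in 5 of 9 and fell in 1 (5 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.25), among them Dpt, dermatopontin (3.31), Lum (1.63) and Pdgfra (1.22). Of the macrophage markers, Cd68 rose by 1.83: it was listed at 0.246, 0.378 and 0 FPKM in the controls and at 9.37, 1.39 and 2.13 in the PDGF-NS libraries. Fcer1g, the other macrophage marker tested, chosen after its value was seen, had a log2 fold change of −0.16 and did not pass.

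In migration and proteolysis, 8 rose, 4 fell and 4 did not pass of 16 (8 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.66). Plat, tissue plasminogen activator, rose by 2.11 and Mmp2 by 1.95. Of 15 inflammatory genes 7 rose, 2 fell and 6 did not pass (7 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.72), and its median of 0.12 turned to −0.01 under median ratio scaling. The monocyte chemokines Ccl2 and Ccl7 rose by 1.83 and 3.33, and the cytokine Il6 by 2.27, from 1.02 to 9.66 FPKM. Interferon-stimulated genes rose in 11 of 16 and fell in 0 (12 higher and 0 lower adjusted over the list alone), with a median of 0.81, or 0.70 after median ratio scaling (camera adjusted p = 0.00036, and adjusted p = 0.25 with an estimated correlation). IFI44 rose by 1.92, and the immunoproteasome subunit Psmb9 by 1.66.

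For cholesterol synthesis and uptake, 15 rose, 0 fell and 8 did not pass of 23 (19 higher and 0 lower adjusted over the list alone), with a median of 0.79, or 0.67 after median ratio scaling (camera adjusted p = 2e-04, and adjusted p = 0.51 with an estimated correlation). Hsd17b7, an enzyme of the pathway, rose by 2.79, and Insig1, which retains the SREBP complex in the endoplasmic reticulum, by 1.40. Fatty acid genes rose in 7 of 11 and fell in 0 (9 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0074, and adjusted p = 0.5 with an estimated correlation), Fads1 by 1.87. Under the other scalings 1 member of that list fell. Glycolysis genes rose in 8 of 16 and fell in 0 (12 higher and 0 lower adjusted over the list alone; median 0.76, or 0.64 after median ratio scaling). The test gave camera adjusted p = 0.0064, and adjusted p = 0.5 with an estimated correlation, and Pfkl, a phosphofructokinase, rose by 1.21. Bnip3, which encodes no glycolytic enzyme, counted among the 8 and rose by 1.78.

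In this set Mki67 was at 17.3 ± 3.61 FPKM, a log2 fold change of 0.14 (adjusted p = 0.67, 95% interval −0.36 to 0.64). Of 26 G2 and M phase genes, 0 rose, 3 fell and 23 did not pass and 0 passed adjusted over the list alone, with a median of −0.22 (camera adjusted p = 0.015, and adjusted p = 0.71 with an estimated correlation). The call ended without control library 2 (0.056) or PDGF-NS library 1 (0.1). Of 28 DNA replication genes, 2 rose, 5 fell and 21 did not pass (2 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.012, and adjusted p = 0.59 with an estimated correlation), and that call ended with a mean of at least 5 FPKM (0.32). In the receptor pathways Igf1r fell to 31.2 ± 2.66 FPKM (−0.98), Irs1 by 1.12 and Irs2 by 1.12, while Pdgfrb did not pass (−0.38, adjusted p = 0.15). Igfbp2, an IGF-binding protein, fell from 95.8 ± 41.7 to 6.62 ± 1.05 FPKM (−3.59). The IGF axis (4 rose, 6 fell and 6 did not pass; 4 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.078) and the PDGF axis (2 rose, 2 fell and 3 did not pass; 2 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.35) were not called, though without control library 3 the IGF axis was called lower (0.047).

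Other genes with large changes were Acpp, an acid phosphatase (4.48), Anpep, aminopeptidase N (4.48), Rasd1, a Ras-like protein induced by glucocorticoid (4.26), and G0s2 (4.61). St8sia2 (−5.01), the growth factor Bmp3 (−4.28), Acta1 (−4.26), Nkd2 (−4.00), the proteoglycan Fmod (−3.85) and the matrix protein Abi3bp (−3.57) fell. Altogether 2355 genes lay higher and 1166 lower than control, 3521 in total. At a log2 fold change of at least 1 the counts were 783 and 459. The median of all genes was 0.13. Other scalings removed it and brought the share higher from 66.9% to 50.9% (1752 and 1687, median ratio), 49.1% (1692 and 1752, quantile) and 50.3% (1736 and 1712, rescaled to one common sum). Median ratio scaling and quantile normalization take out such a shift by design, whatever its cause. Under median ratio scaling 1752 of the 2355 higher and 1166 of the 1166 lower calls stayed. It shifts the fold changes downward here, so lower calls could hardly be lost. These scalings also changed list counts by over 1.5 times: 5 G2 and M phase genes fell in place of 3, 8 or 9 DNA replication genes in place of 5, and 4 or 5 inflammatory genes in place of 2, and after rescaling to one common sum 5 ERK-induced genes rose in place of 8.

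**Figure D2:**
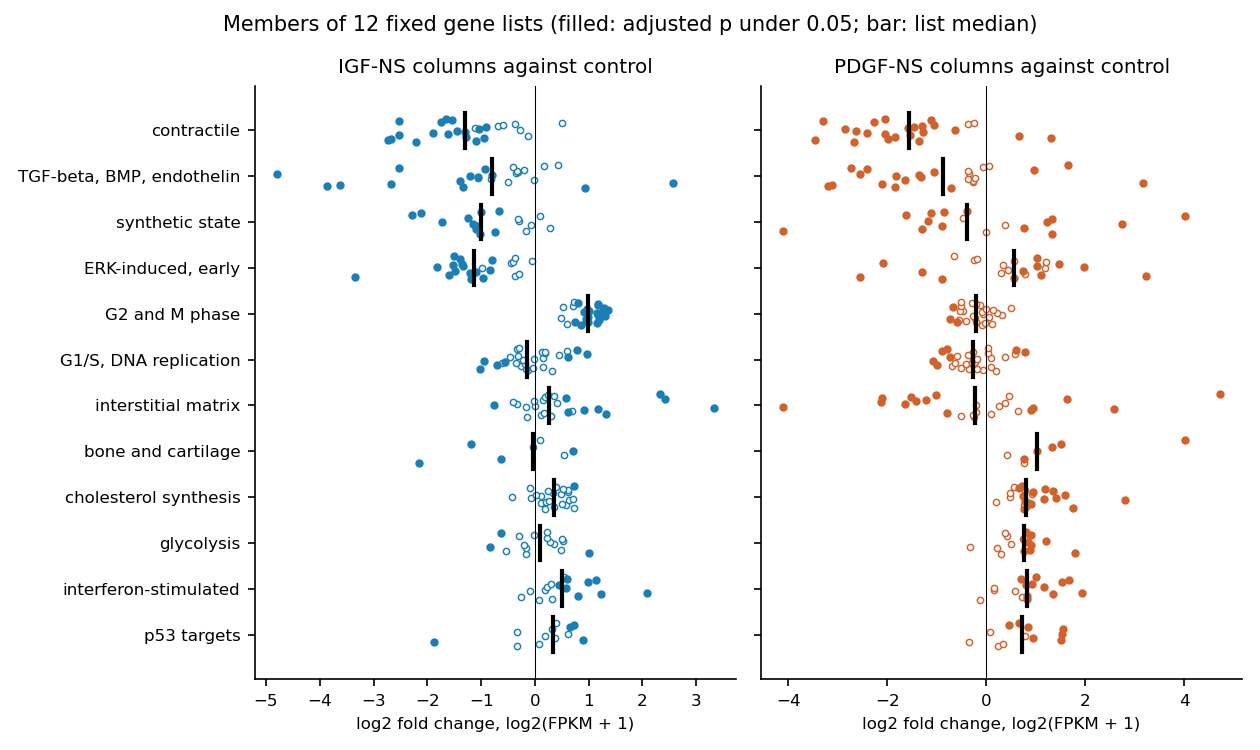
Log2 fold changes of the tested members of 12 fixed gene lists against control, on the log2(FPKM + 1) scale, for the IGF-NS libraries (PDGF-BB by record, left) and the PDGF-NS libraries (IGF-1 by record, right). Each point is a gene, filled where its adjusted p passed, and each bar is the list's median, which for contractile genes was −1.30 on the left and −1.57 on the right.

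The third comparison set the treated sets against each other, PDGF-NS (IGF-1, 24 h, by record) minus IGF-NS (PDGF-BB, 48 h, by record), and so bears on whether the responses diverged. Every direction here would carry the other growth factor's name if the column names were right. The PDGF-NS libraries had more Spp1 (9480 against 634 FPKM, log2 difference 3.92 ± 0.31, adjusted p = 3.4e-05) and more Lgals3 (3.88 ± 0.20), and less Eln (115 against 1740 FPKM, −3.95 ± 0.20, adjusted p = 3.4e-06). They also had less Mki67 (−1.22 ± 0.22, adjusted p = 0.0047). Each of these values is for n = 3 against 3.

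Of 26 G2 and M phase genes, 0 lay higher, 23 lay lower and 3 did not pass in the PDGF-NS libraries (0 higher and 26 lower adjusted over the list alone), with a median of −1.21 (camera adjusted p = 3.1e-15, and adjusted p = 0.22 with an estimated correlation). Examples were Kif20a (−1.74), Ccnb1, cyclin B1 (−1.76), and Cdc20, an activator of the anaphase-promoting complex (−1.69). For DNA replication 1 lay higher, 2 lay lower and 25 did not pass of 28 (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.18), and without IGF-NS library 1 the list was called lower (0.015). ERK-induced and immediate-early genes went the other way: of 22, 14 lay higher, 1 lay lower and 7 did not pass (19 higher and 1 lower adjusted over the list alone). Their median difference was 1.45 (camera adjusted p = 3e-10, and adjusted p = 0.11 with an estimated correlation). Fosl1 was at 25.1 ± 6.15 FPKM in PDGF-NS and 0.872 ± 0.381 in IGF-NS (3.79 ± 0.30), and Dusp5 (3.60), Junb, an AP-1 subunit (2.82), and Dusp6 (2.71) were higher too. Myc, the member that lay lower, differed by −1.65 (chosen for this comparison after its value was seen). Heat shock and early stress genes, which handling also induces and which share Fos with this list, moved with it: of 11, 6 lay higher, 0 lay lower and 5 did not pass (8 higher and 0 lower adjusted over the list alone), with a median of 0.97 (camera adjusted p = 0.00037, and adjusted p = 0.19 with an estimated correlation).

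Contractile genes went both ways between the sets. Of 24, 4 lay higher, 8 lay lower and 12 did not pass (5 higher and 10 lower adjusted over the list alone), with a median of −0.46 and a mean of −0.24 (camera adjusted p = 0.025, and adjusted p = 0.42 with an estimated correlation). That call ended after rescaling to one common sum (0.069) and without IGF-NS library 3 (0.086). Myocd (−1.81) and Myl9, the regulatory myosin light chain (−1.19), lay lower in the PDGF-NS libraries, and Des (2.25) and Itga8 (0.96) higher. Synthetic-state genes lay higher in 9 of 17, lower in 2 (10 higher and 2 lower adjusted over the list alone), with a median of 0.67 (camera adjusted p = 4.5e-05, and adjusted p = 0.11 with an estimated correlation), Mgp by 2.94. Bone and cartilage genes lay higher in 5 of 7 and lower in 0 (5 higher and 0 lower adjusted over the list alone; median 1.40; camera adjusted p = 6.2e-06, and adjusted p = 0.061 with an estimated correlation). Acan and Sox9 were 2.92 and 2.70 higher.

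Interstitial matrix genes lay lower in 13 of 24 and higher in 3 (3 higher and 14 lower adjusted over the list alone), with a median of −0.83 (camera adjusted p = 1.9e-05, and adjusted p = 0.11 with an estimated correlation). They included Dcn (−2.38) and Mfap4, a microfibril-associated glycoprotein (−2.68). Fibroblast markers were split, 2 lay higher, 4 lay lower and 3 did not pass of 9 (3 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.66), and basement membrane genes were not called (1 lay higher, 2 lay lower and 8 did not pass of 11; 2 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.27). Migration and proteolysis genes lay higher in 8 of 16 and lower in 2 (9 higher and 2 lower adjusted over the list alone), with a median of 0.80 (camera adjusted p = 0.0017, and adjusted p = 0.11 with an estimated correlation). Cd44, the hyaluronan receptor (2.34), and Plaur (1.72) were examples, and with a mean of at least 5 FPKM the call ended (0.065). Among 15 inflammatory genes, 5 lay higher, 3 lay lower and 7 did not pass (8 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.092): Ccl2 (2.88) lay higher, and Cxcl12, a chemokine of stromal cells (−1.70), lower. That list was called after rescaling to one common sum (0.027) and without IGF-NS library 3 or PDGF-NS library 2.

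Glycolysis genes lay higher in 6 of 16 and lower in 0 (9 higher and 0 lower adjusted over the list alone, median 0.57, camera adjusted p = 7.3e-06, and adjusted p = 0.22 with an estimated correlation), among them the glucose transporter Slc2a1 (1.01). Bnip3 was another of the 6 (0.77, chosen for this comparison after its value was seen). Cholesterol genes lay higher in 7 of 23 and lower in 0 (9 higher and 0 lower adjusted over the list alone; median 0.50; camera adjusted p = 4.5e-05, and adjusted p = 0.42 with an estimated correlation), such as Insig1 (1.46). TGF-beta, BMP and endothelin genes showed no list difference (4 lay higher, 3 lay lower and 17 did not pass of 24; 6 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.54). The IGF axis was not called (4 lay higher, 4 lay lower and 8 did not pass of 16; 4 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.092), though without IGF-NS library 2 it was. Within it Igf1r (0.72) and Irs2 (1.26) lay higher in the PDGF-NS libraries and Igfbp2 (−3.28) lower, and Irs1 did not pass (−0.69). For the PDGF axis 1 lay higher, 1 lay lower and 5 did not pass of 7 (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.72), and the receptors Pdgfra (0.36) and Pdgfrb (−0.48) did not pass.

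By size alone, Hsd11b1 (5.39), Cdhr1, a cadherin-related protein (4.49), Nt5e, the ectonucleotidase that forms adenosine (4.23), Rasd1 (4.12), CLIC5, a chloride intracellular channel protein (4.05), and Acpp (4.03) led the genes higher in PDGF-NS. After Eln, the genes lower in PDGF-NS were led by Fmod (−3.51), Pi15 (−3.29), Igfbp2, Prima1, a membrane anchor of acetylcholinesterase (−3.22), Thbd, thrombomodulin (−3.02), and Sfrp2 (−3.00). In total 948 genes lay higher and 859 lower, 1807 together, and 427 and 300 differed by at least 1 on the log2 scale. Rescaling to one common sum moved the median from −0.02 to −0.15 and the split to 748 and 1488, 33.5% higher in place of 52.5%. It also put 7 IGF axis genes lower in place of 4, and 6 TGF-beta, BMP and endothelin genes in place of 3.

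Both treated sets share the 3 controls. In the same direction, 1138 genes lay higher and 517 lower in both, where independent lists of these lengths would share 409.1 and 87.2. In opposite directions, 36 genes lay higher in IGF-NS and lower in PDGF-NS (independent lists 202.5) and 45 the other way (176.2). The sets also differed from each other by test in all 81 of these. A gene called on opposite sides of control in one fit could hardly fail that test, so it adds no support. Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson r = 0.60 against 0.50 in simulations of unchanged groups with shared controls, and their covariance was 0.242 against 0.029, a difference of 0.213. The controls are too few to split, so part of the overlap may come from the shared controls.

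The 81 opposite genes included several with large differences between the sets. Lgals3 fell to 20.6 ± 2.13 FPKM in the IGF-NS libraries and rose in the PDGF-NS libraries, and Mgp, Fosl1, Nt5e and Cdhr1 moved likewise: Nt5e fell by 1.43 and rose by 2.80, and Cdhr1 fell by 1.25 and rose by 3.25. Gja5, the gap junction protein connexin 40, fell by 1.95 and rose by 1.88. Prima1 rose by 1.87 in IGF-NS and fell by 1.35 in PDGF-NS.

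**Figure D3:**
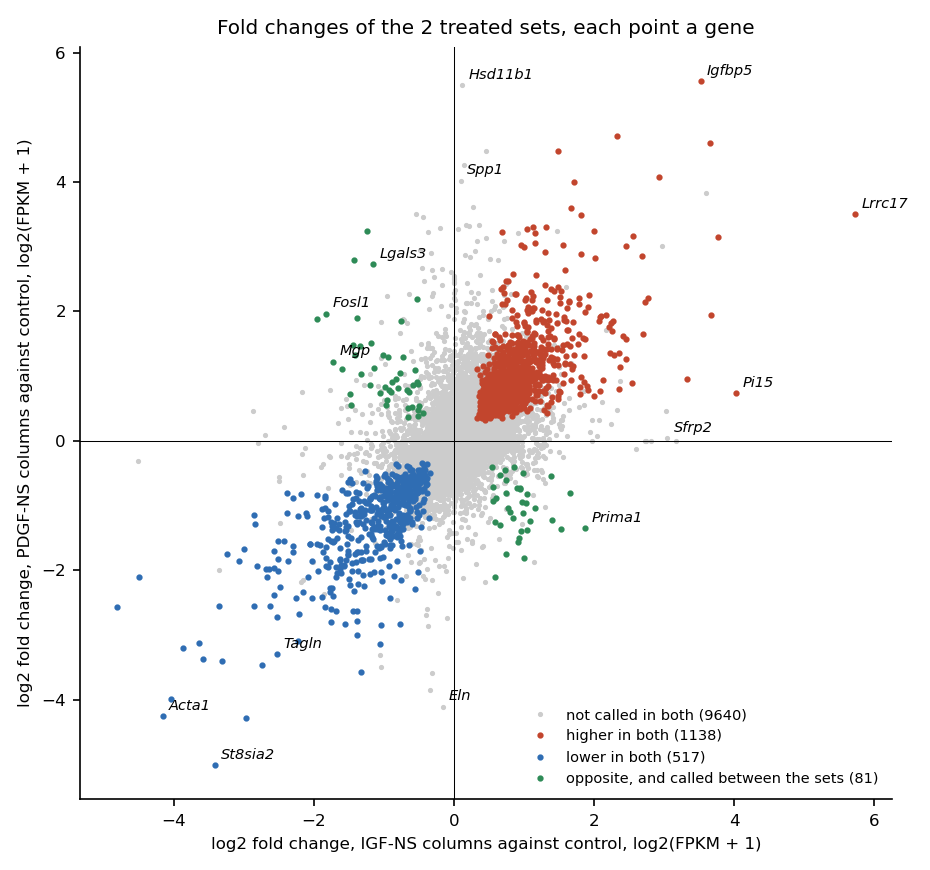
Each point is 1 of 11376 genes, with its log2 fold change against control in the IGF-NS libraries (PDGF-BB by record) on the x axis and in the PDGF-NS libraries (IGF-1 by record) on the y axis. Red marks the 1138 genes higher in both, blue the 517 lower in both and green the 81 that moved in opposite directions. These 81 also differed between the sets by test, which their opposite calls all but imply.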

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

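The tests of a factor per library, of the 200 most abundant transcripts and of the ERK-induced genes were chosen after the results they address had been seen, as was the demand that the contractile check also pass with an estimated correlation and the look at other gene groups and at receptor genes beside it, while the contractile check itself and the count of other splits were set beforehand.

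The sample records and the column names give the growth factors of the treated sets the opposite way round. PDGF-BB is the classical repressor of contractile genes, so if the records were swapped and the column names right, the contractile list should lie lower in the PDGF-NS than in the IGF-NS libraries. The median log2 difference was −0.46 with camera adjusted p = 0.025, which meets that condition as first written, but adjusted p = 0.42 with an estimated correlation, and the call ended after rescaling to one common sum (0.069) and without IGF-NS library 3 (0.086). Other groups differed in both directions. In PDGF-NS the ERK-induced genes (median 1.45, camera adjusted p = 3e-10, and adjusted p = 0.11 with an estimated correlation) and the synthetic-state genes (0.67, 4.5e-05 and 0.11) lay higher and Myocd lower (−1.81). FoxO targets, which AKT signalling represses, lay higher there too (0.44, 0.0031 and 0.33). But the G2 and M phase genes lay lower (−1.21, 3.1e-15 and 0.22), and DNA replication genes were not called (−0.16, 0.18). Whether one growth factor raises cell cycle genes more than the other was not tested, so their direction favours neither naming. Harvest time differs along with the growth factor, so which names are right cannot be told apart from these values, and no library was reassigned.

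For the same purpose the receptor and adaptor genes are given per library. Igf1r was at 64, 57.5 and 66.4 FPKM in control, 17, 17.4 and 21.5 in IGF-NS and 32.2, 33.2 and 28.2 in PDGF-NS. Irs1 was at 26, 17 and 14.6, then 11.9, 11.5 and 18.3, then 6.45, 10.2 and 7.85, and Irs2 at 58, 32.3 and 38.7, then 6.52, 6.19 and 9.14, then 16.5, 21.3 and 18.3. Pdgfra was at 11.6, 12.8 and 9.98, then 24.3, 20.6 and 19.5, then 26.6, 30.2 and 26.7, and Pdgfrb at 557, 386 and 360, then 523, 370 and 493, then 319, 348 and 318.

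More genes lay higher than lower against control in both treated sets, 69.9% and 66.9% of the calls. A factor per library left by the authors' scaling is a candidate explanation for both sets that the bins of expression cannot decide. The median log2 change was nearly alike in 5 bins, with the highest and lowest medians 0.04 apart in the IGF-NS and 0.04 apart in the PDGF-NS libraries. A true rise of most transcripts relative to the rest would give like bins too. On the log2(FPKM + 1) scale one factor would move the bin of lowest expression somewhat less. That bin was at 0.11 against 0.15 in the bin of highest expression in PDGF-NS, but at 0.15 against 0.12 in IGF-NS. A fall of the 200 most abundant transcripts, which would raise all others, is argued against in PDGF-NS, where they took 1.1 percentage points more of the FPKM than in control (48.7% against 47.6%, libraries 47.9 to 49.3 against 46.9 to 48.1). There, scaling by the sum of all other genes brought the median from 0.13 to 0.03, but scaling by the sum of all genes, these 200 included, brought it to 0.01, so that fall is not specific to them. In IGF-NS they took less, −2.0 points (45.5% against 47.6%). Leaving them out of the scaling brought the median there only from 0.15 to 0.09, so this part stays open. A true rise of most transcripts relative to the rest stays open too and was not tested. An equal rise of all transcripts per cell would cancel in FPKM, which are per unit of library size, so it could not give this shift.

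ERK-induced and immediate-early genes lay higher in the PDGF-NS than in the IGF-NS libraries, by a median log2 difference of 1.45. The scaling of the libraries is argued against by the median of all genes, −0.02, since a factor per library moves all genes together. The lowest list median over 3 other scalings was 1.34. These scalings put the median of all genes between −0.15 and 0, so they could hardly have removed the difference and add little. A cause in 1 aberrant library is argued against too, since the lowest median without any 1 of the 6 treated libraries was 1.18. Handling at harvest stays open: heat shock and early stress genes, which handling induces, lay higher in the same libraries by a median of 0.97 (camera adjusted p = 0.00037, and adjusted p = 0.19 with an estimated correlation). The growth factor, the time of harvest (24 h against 48 h by record) and the doubt over the names stay open too, and none of these was tested. That signalling through ERK differed between the sets is a hypothesis that these values do not test, and phosphorylated ERK measured in both treatments at matched harvest times would test it.

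For each comparison the 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 2827, 3521 and 1807 genes, 1 of 10 splits reached that number in each case, the real one itself, and the highest of the others called 1 gene.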

How the results depend on the processing

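The alternative without genes listed at 0 in part of a group was chosen after seeing the data, and all others were set before. It gave 2024 higher and 867 lower genes in IGF-NS against control, 2367 and 1185 in PDGF-NS against control, and 947 and 883 between the sets. Array weights raised every count by over 1.5 times: to 3842 and 1637, 3661 and 1799, and 2002 and 2159, to 2252 higher in both, 909 lower in both and 298 in opposite directions. The weights ran from 0.27 for control library 1 to 3.93 for IGF-NS library 1. Requiring a log2 fold change of 1 left 435 and 353, 783 and 459, and 427 and 300. Scaling moved these counts: IGF-NS higher 1214 (quantile) and 1143 (median ratio), PDGF-NS lower 1752 (quantile), lower between the sets 1488 (one common sum), and higher in both 657 (quantile) and 652 (median ratio). Leaving out 1 library leaves 2 in its group and gave ranges of 1172 (without IGF-NS 1) to 1967 for IGF-NS higher, 1520 (without PDGF-NS 3) to 2491 for PDGF-NS higher, 541 (without PDGF-NS 3, and 625 without PDGF-NS 2) to 1101 for higher between the sets, and 468 (without PDGF-NS 3, and 548, 567 and 568 without IGF-NS 1, PDGF-NS 1 and PDGF-NS 2) to 1051 for lower between the sets. For genes higher in both the range was 736 (without IGF-NS 1) to 1150, and for opposite genes 40 (without control 2, and 50 and 47 without control 3 and PDGF-NS 3) to 84. The replicate number as a block called 1699 and 758, 2149 and 1072, and 822 and 708 genes, with 979 higher in both, 457 lower in both and 77 opposite. The numbers gave no sign of pairing: 2 of 9 same-number pairs correlated over 0.1 (−0.28 to 0.25), and 2 of 9 libraries correlated best with their own number. With 3 libraries per group this check cannot exclude a pairing. For gene lists, the direction and side of the threshold stayed in 1795 of the repeated tests. The call was lost in 67 and gained in 42, an uncalled direction turned in 28, and a direction called in either fit reversed in 0. For named genes these were 13566, 665, 220, 140 and 1. Apart from the fixed set, the named genes were picked for calls and large changes in these same data. That choice favours unchanged results, so this tally does not stand for all genes. Of the 67 lost list calls, 40 were lost with the estimated correlation. Robust moderation does not enter the list test, so its 84 repeats could not change, and the list tests were not repeated with array weights. The reversed named gene was Msmo1 in IGF-NS against control, −0.66 (adjusted p = 0.029) with array weights. As reported it stood at 0.02 and was not called, and the cause was not tested. Read depth is unknown, which leaves the counting error of low genes unmeasured.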

Other observations

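The tests in this part use lists and thresholds fixed beforehand, and the groups were picked for description after their results were seen. Amino acid and stress genes under the transcription factor ATF4 were tested as a list. Between the PDGF-NS libraries (IGF-1 by record) and the IGF-NS libraries (PDGF-BB by record), 1 lay higher, 9 lay lower and 14 did not pass of 24, with 1 higher and 15 lower adjusted over the list alone and a median of −0.51 (camera adjusted p = 4.9e-05, and adjusted p = 0.35 with an estimated correlation). After rescaling to one common sum 14 lay lower. Phgdh, the first enzyme of serine synthesis, went from 68.1 FPKM in IGF-NS to 26 in PDGF-NS (−1.38), and Chac1, which degrades glutathione, differed by −1.25. Against control the list was called in neither set as deposited (IGF-NS 8 rose, 1 fell and 15 did not pass, 8 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.15, and PDGF-NS 2 rose, 4 fell and 18 did not pass, 2 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.064). It was called higher in IGF-NS under quantile normalization (0.036), with no filter on low values (0.043) and without control library 1 (0.043), and lower in PDGF-NS without control library 3 (0.016), PDGF-NS library 2 (0.018) or PDGF-NS library 3 (0.037). Slc7a1, a transporter of cationic amino acids, fell in both (−1.20 and −2.05), and Ddit4, an inhibitor of mTORC1, rose in both (1.61 and 1.72). Nucleolar ribosome biogenesis genes lay lower on balance in PDGF-NS. Against control 1 rose, 8 fell and 14 did not pass of 23 (2 higher and 8 lower adjusted over the list alone, median −0.41, camera adjusted p = 3e-04, and adjusted p = 0.25 with an estimated correlation), with Nop2, a methyltransferase of ribosomal RNA, falling from 27.2 ± 5.94 to 12.9 ± 0.535 FPKM. Between the sets 0 lay higher, 7 lay lower and 16 did not pass (0 higher and 11 lower adjusted over the list alone, 11 lower after rescaling to one common sum, camera adjusted p = 0.00014, and adjusted p = 0.19 with an estimated correlation), and in IGF-NS against control 1 rose, 1 fell and 21 did not pass (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.46). Chaperones of the endoplasmic reticulum were called in no comparison (4 rose and 1 fell of 16 in IGF-NS, 1 and 0 in PDGF-NS, and 1 lay higher and 2 lower between the sets), and neither were nuclear genes of oxidative phosphorylation (4 and 0 of 17, 3 and 0, and 0 and 0). Adjusted over the list alone these counts were 4 and 1, 0 and 0, and 1 and 2 for the chaperones and 4 and 0, 2 and 0, and 0 and 0 for oxidative phosphorylation. The median of the chaperones turned from 0.04 to −0.12 in IGF-NS and that of oxidative phosphorylation from 0.13 to −0.03 under median ratio scaling. In IGF-NS 1 gene of oxidative phosphorylation rose under that scaling and under quantile normalization, and between the sets 4 chaperones lay lower after rescaling to one common sum.

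Notch pathway genes fell on balance in the PDGF-NS libraries. Of 8, 1 rose, 4 fell and 3 did not pass (1 higher and 4 lower adjusted over the list alone), with a median of −0.39 (camera adjusted p = 0.018, and adjusted p = 0.48 with an estimated correlation), and the call ended after rescaling to one common sum (0.15) and with no filter on low values (0.09). Notch3, the receptor typical of vascular smooth muscle, fell from 63.5 ± 25.1 to 16.3 ± 3.19 FPKM (−1.85), its ligand Jag1 by 2.03 and its target Hey2 by 2.64 on the log2 scale. In IGF-NS 2 rose, 2 fell and 4 did not pass (3 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.47), and between the sets 0 lay higher, 4 lay lower and 4 did not pass (0 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0021, and adjusted p = 0.22 with an estimated correlation). Targets of p53 rose in PDGF-NS in 7 of 12 cases and fell in 0 (7 higher and 0 lower adjusted over the list alone, median 0.71, or 0.59 after median ratio scaling, camera adjusted p = 0.015, and adjusted p = 0.48 with an estimated correlation). Mdm2, the ubiquitin ligase of p53, rose by 1.52 and Cdkn1a, the cell cycle inhibitor p21, by 0.93. In IGF-NS 3 rose, 1 fell and 8 did not pass (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.74), and between the sets 2 lay higher, 0 lay lower and 10 did not pass (5 higher and 0 lower adjusted over the list alone, 4 higher after median ratio scaling, camera adjusted p = 0.0026, and adjusted p = 0.26 with an estimated correlation). FoxO targets, which AKT signalling represses, rose in 10 of 19 and fell in 1 in PDGF-NS (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.026, and adjusted p = 0.5 with an estimated correlation), a call that ended without control library 2 (0.069), control library 3 (0.051) or PDGF-NS library 1 (0.058). Sesn3, a stress-induced sestrin, rose by 1.85 there and by 2.06 in IGF-NS, where 6 rose, 1 fell and 12 did not pass (6 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.78, median 0.12 and −0.03 after median ratio scaling). Between the sets 7 lay higher, 0 lay lower and 12 did not pass (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0031, and adjusted p = 0.33 with an estimated correlation).

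Channels and calcium handling genes fell in 6 of 17 and rose in 1 in IGF-NS (1 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.0012, and adjusted p = 0.36 with an estimated correlation), went both ways in PDGF-NS (6 rose, 4 fell and 7 did not pass, 6 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.72, median 0.09 and −0.04 after median ratio scaling), and 6 lay higher, 0 lay lower and 11 did not pass between the sets (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0026, and adjusted p = 0.29 with an estimated correlation). Trpc6, a receptor-operated cation channel, fell from 20.5 ± 9.2 to 2.13 ± 0.0916 FPKM in IGF-NS (−2.70) and stood at 20.9 ± 3.64 FPKM in PDGF-NS, where Trpv2, another cation channel, rose by 2.66. Kcnmb1, the beta subunit of the smooth muscle BK channel, fell in both (−1.61 and −2.04). For heat shock and early stress genes, described above for the other comparisons, 4 rose, 1 fell and 6 did not pass of 11 in PDGF-NS against control (4 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.68). Between the sets Hspb1, a small heat shock protein, was at 622 FPKM in PDGF-NS against 163 in IGF-NS (1.94). Hmox1, heme oxygenase 1, rose in both sets, by 1.38 and 2.35. Fatty acid genes were not called between the sets (1 lay higher, 2 lay lower and 8 did not pass of 11, 1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.54). Interferon-stimulated genes lay at camera adjusted p = 0.051 between the sets (1 lay higher, 1 lay lower and 14 did not pass, 1 higher and 1 lower adjusted over the list alone) and were called higher in PDGF-NS under 3 other scalings (0.039 to 0.049), with no filter on low values (0.012), in a fit of the compared groups alone (0.027), without genes listed at 0 in part of a group (0.047), and without control library 1, 2 or 3, IGF-NS library 1 or PDGF-NS library 2 or 3 (0.019 to 0.047).

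Markers of other cell types were measured too. Pericyte markers were called in no comparison: of 6, 1 rose, 1 fell and 4 did not pass in IGF-NS (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.85), 3 rose, 2 fell and 1 did not pass in PDGF-NS (3 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.82), and 3 lay higher, 2 lay lower and 1 did not pass between the sets (3 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.54). Anpep, one of them, rose from 7.25 ± 1.17 to 187 ± 48.2 FPKM in PDGF-NS and Mcam fell by 2.60. Of 2 endothelial markers tested, Erg, a transcription factor, fell by 1.24 in IGF-NS, and 0 passed in PDGF-NS or between the sets, so these are values with no list test. The macrophage list had 2 tested genes, of which 0 passed in IGF-NS and 1, Cd68, in PDGF-NS and between the sets. Among 2 cardiomyocyte markers, 1, Tnnt2, lay lower in PDGF-NS than in IGF-NS (−1.83).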
